A study of Mus musculus with 32 samples.

How the data were processed

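Poly(A) RNA from the MC38 mouse colon adenocarcinoma line was sequenced in 4 groups: 13 parental and 12 anti-PD-1 resistant subcutaneous tumors from untreated mice, and 2 parental and 5 resistant cultures. Per the labels, RNA was extracted with Qiagen kits and DNase treatment, and libraries were made with KAPA RNA HyperPrep kits. The authors deposited 1 table of TPM, the length-scaled share of each transcript in its library, by gene symbol for 32 libraries, and every column was used. STAR and the build GRCh38 are named per the submitters' processing notes, with no version or role. GRCh38 is a human build, while the symbols are mouse symbols, of which 98.4% are in GENCODE mouse release 21. The quantifier and annotation were not given, so no coordinates are printed. The TPM columns sum to a fixed total, and values reach down to 8.57e-317, which marks them as estimated abundances, so neither read totals nor counts can be recovered. Depth per sample is unknown, and the precision of each value rests on the spread between libraries alone.

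The comparisons, tests, named genes, gene lists and most alternatives were fixed before the data were examined. Groups came from the line and setting in the labels. The labels do not say that the cultured libraries came from separate cultures, so p-values there measure only the spread between these samples, which may be technical. Nothing in the labels pairs samples, and replicate numbers follow the order of deposition. Each comparison was fitted to its own libraries with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with empirical Bayes moderation and an intensity trend, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A gene was tested if it reached 1 TPM in at least as many libraries as the smaller group holds. The interaction used all 32 libraries in 1 fit. Log2 fold changes are resistant minus parental, or tumor minus culture, and the interaction is the line difference in tumors minus that in culture.

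The genes named were the 10 largest rises and 10 largest falls of the tumor comparison, and 5 of each in the others, among called genes with a mean of at least 5 TPM in the higher group (for the interaction, in any group). Gene models without an established symbol, pseudogenes, antigen receptor segments, Y-linked genes and Xist were skipped. Fixed genes of antigen presentation, interferon signaling and lymphocytes were added for both line comparisons, and up to 4 members with the lowest adjusted p for each gene list described. The 40 lists held cell type, signaling and metabolic genes. Irf8, Cox4i1, Mvd and Acta1, which belong to 4 of the lists, were not analysed here. Lists with at least 4 tested members were tested with limma camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation and with limma fry. Members passing the threshold were counted after adjustment over all genes and adjusted over the list alone. A list score is the mean log2(TPM + 1) of the members in a tumor, compared between lines by a two-sided permutation test of 100000 resamples. It takes in members too low to be tested with limma. Correlations of scores were computed within each line with permutation p-values for 8 relations. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for scores, resampling and figures.

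The GC index of a library is the median log2 level of 2374 GC-rich genes (GC fraction over 0.55) minus that of 1078 GC-poor genes (under 0.42). Each gene was first set against its mean over the tumor libraries. GC content came from GENCODE transcripts for 98.4% of the 10046 genes with a mean of at least 5 TPM in tumors. Alternatives were a pseudocount of 0.1, no filter, a filter at 5 TPM, quantile normalization, median-of-ratios scaling, robust moderation, array weights, a rank-sum test, 1 fit over all libraries, Ptprc as a covariate, a 2-fold minimum and leaving out each library in turn. The GC index as a covariate and leaving out the 4 parental tumors with an index above 0.5 were added after the data were seen. The tests were also tested on simulated data of the same group sizes. Changes were put only into well expressed genes, with noise independent between genes and the same spread in both groups, so the shares recovered hold for such data. In the tumor design, simulated over 12095 genes, limma recovered 92% of 2-fold and 99% of 4-fold changes. In the culture design, over 11201 genes, it recovered 61% and 95%. In the parental tumor against culture design, over 14348 genes, it recovered 40% and 90%, and in the resistant one, over 12312 genes, 92% and 99%.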

Results

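RNA was sequenced from MC38, a mouse colon adenocarcinoma line, in a parental form and in a form resistant to anti-PD-1, an antibody that blocks the T cell checkpoint receptor PD-1. The lines were compared as subcutaneous tumors grown in untreated C57BL6/J mice, with 13 parental and 12 resistant tumors, and as cultured cells, with 2 parental and 5 resistant libraries. The deposited table gave mouse gene symbols in TPM, a transcript's length-scaled share of its library, for all 32 libraries. The values are estimated abundances with no read totals, so the depth of each library is unknown and no counting interval can be given. Genes reaching 1 TPM numbered 12434 ± 464 (SD) in parental tumors, 12171 ± 339 in resistant tumors, 10816 ± 229 in parental culture and 10578 ± 131 in resistant culture. Within groups, the median correlation between libraries across genes was 0.973 in parental tumors, 0.984 in resistant tumors, 0.991 in resistant culture, and 0.988 for the pair of parental cultures. Mitochondrially encoded genes took 7.19 ± 2.01% of TPM in parental tumors and 10.01 ± 2.68% in resistant tumors.

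The main comparison asked how tumors of the resistant line differ from parental tumors before any treatment. Prl2c2, a placental prolactin-family hormone, fell from 612 ± 422 TPM (SD, n = 13) in parental tumors to 29.0 ± 11.01 TPM (n = 12) in resistant tumors. Itgb4, the beta 4 integrin that anchors epithelial cells to the basement membrane, fell from 50.2 ± 30.3 to 1.66 ± 0.60 TPM. Igfbp4, a secreted binder of insulin-like growth factors, fell from 371 ± 140 to 52.8 ± 11.1 TPM. In the other direction, Has2, which makes the matrix sugar hyaluronan, rose from 12.4 ± 16.95 to 69.0 ± 15.7 TPM, and Rgs5, a pericyte-associated regulator of G protein signaling, rose from 12.6 ± 6.71 to 78.6 ± 16.998 TPM. The limma log2 fold changes were -4.11 ± 0.31 (SE) for Prl2c2 (adjusted p = 1.70e-10), -3.93 ± 0.35 for Itgb4 (4.14e-09), -2.73 ± 0.16 for Igfbp4 (5.53e-13), 2.99 ± 0.36 for Has2 (6.49e-07) and 2.69 ± 0.23 for Rgs5 (3.38e-09). The other large falls were in the testis cytochrome c gene Cyct (-3.70), the granzyme gene Gzmg (-3.09), Fam129a (-3.05), Prl2c3 (-2.996), the ciliary gene Cfap45 (-2.96), the adhesion gene Ncam1 (-2.76) and Prr19 (-2.72). The other large rises were in the diacylglycerol kinase gene Dgki (3.01), the splicing factor Rbfox1 (2.74), the lysophospholipase gene Enpp2 (2.46), the transporter gene Slc47a1 (2.44), Tex14 (2.27), Cpn1 (2.23), the Notch ligand Jag1 (2.20) and the fibrillar collagen Col1a1 (2.18). For 19 of these 20 genes all 12 resistant tumors lay beyond the parental mean, and for 12 genes the lines did not overlap. Chance gives that for 3.85e-05% of genes, but these were selected for their large changes, so the count is no test. Col1a1 was the exception with 10 of 12 tumors beyond the parental mean: its adjusted p was 0.0264, its log2 fold change was 0.29 (adjusted p = 0.437) with the GC index of the library as a covariate, and its adjusted p was 0.051 with no filter. Of 12095 genes tested with limma, 1969 were higher and 1678 lower in resistant tumors. A change of at least 2-fold was met by 186 of the higher and 242 of the lower genes.

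**Figure D1:**
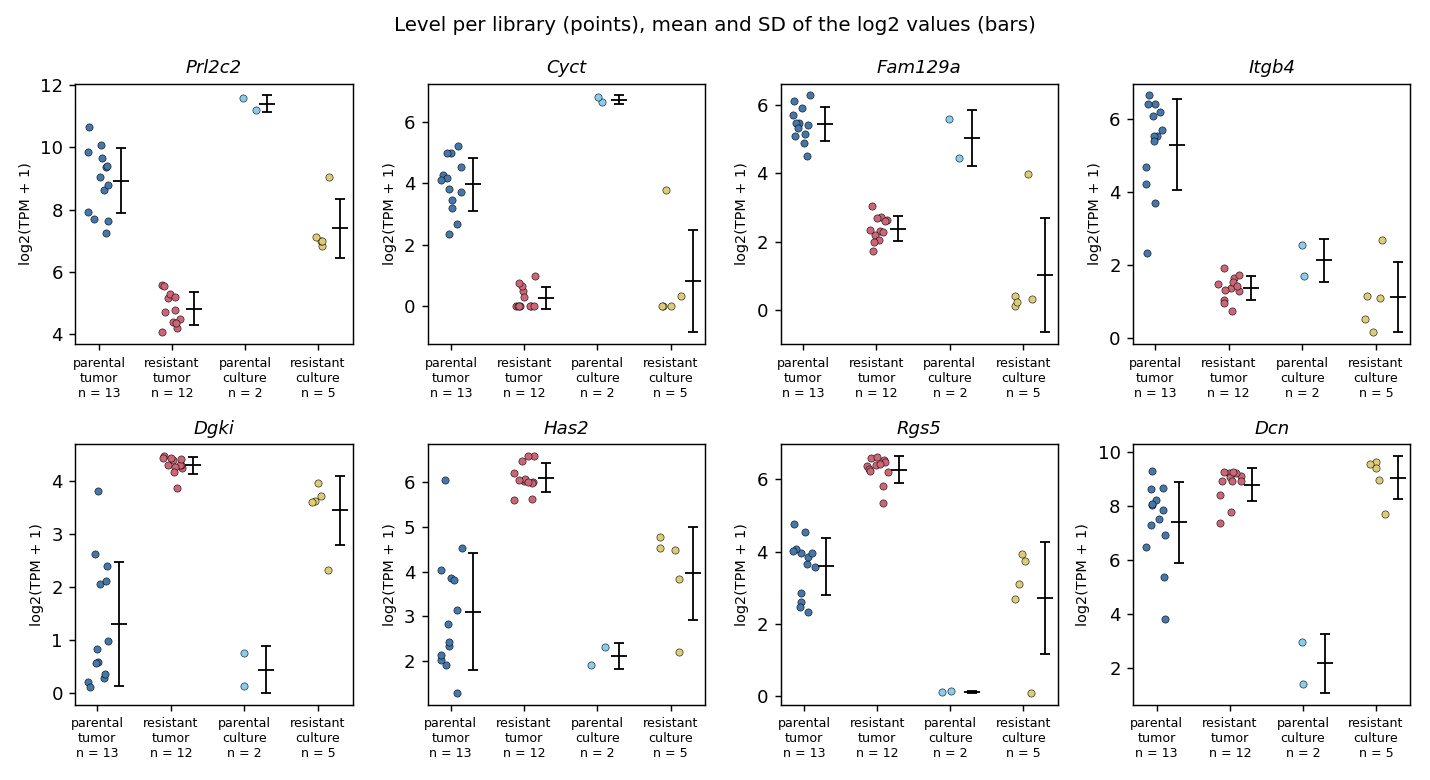
Level of 8 genes in each library as log2(TPM + 1), by line and setting; points are libraries, and bars give the mean and SD of the log2 values. Prl2c2, Cyct, Fam129a, Itgb4, Dgki and Rgs5 did not overlap between the 13 parental and 12 resistant tumors.

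Genes of antigen presentation and interferon signaling, fixed before the data were examined, moved in both directions. Jak2 and Jak1, kinases that carry interferon signals, rose by 0.67 ± 0.08 (SE, log2, limma adjusted p = 7.52e-07) and 0.60 ± 0.13 (0.000981). Jak2 stood at 17.03 ± 2.22 TPM in parental and 27.7 ± 2.72 TPM in resistant tumors. H2-D1, a classical MHC class I heavy chain, fell by 0.34 on the log2 scale (SE 0.10, adjusted p = 0.00793), a call that ended with the GC index as a covariate (-0.22, adjusted p = 0.0667). Gzmb, the granzyme of cytotoxic cells, fell by 0.79 (SE 0.20, adjusted p = 0.00390), from 44.3 ± 17.6 to 23.8 ± 6.29 TPM. No call was made for the PD-1 ligand gene Cd274 (0.28, adjusted p = 0.547), B2m (-0.17, 0.291), H2-K1 (-0.13, 0.384), Irf1 (-0.11, 0.574), the interferon gamma receptor gene Ifngr1 (0.31, 0.224), Cd8a (-0.13, 0.676) or Ifng (0.12, 0.770). With Ptprc, the pan-leukocyte gene, as a covariate, Cd274 (0.77, adjusted p = 0.0140), B2m (-0.30, 0.0250), H2-K1 (-0.25, 0.0427) and Ifngr1 (0.52, 0.0200) did pass. With the GC index as a covariate Cd274 passed in the other direction (-0.51, adjusted p = 0.0128), so its direction in tumors stays open. That covariate also turned the sign of B2m, H2-K1, Irf1, Ifngr1 and Ifng, without a call. Ptprc itself missed the threshold (-0.35, adjusted p = 0.125) and passed without parental tumor replicate 3 (-0.45, 0.0264), without resistant tumor replicate 7 (-0.43, 0.0490), with array weights (-0.47, 0.0104) and with the GC index as a covariate (-0.66, 0.000952). Pdcd1, which encodes PD-1, and Foxp3, the regulatory T cell factor, were too low to be tested, with means of 0.840 and 1.09 TPM in parental tumors and 0.695 and 0.746 TPM in resistant tumors.

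Macrophage genes were lower in resistant tumors. Ms4a7, a macrophage membrane gene, fell from 98.6 ± 23.7 to 35.4 ± 12.4 TPM (log2 -1.50 ± 0.19 SE, limma adjusted p = 1.50e-06), C1qa, a complement component made by macrophages, from 216 ± 66.1 to 94.1 ± 19.6 TPM (-1.14 ± 0.17), and Adgre1 and Cd68 fell by 1.19 and 1.06. Cd68 also fell in culture, where there are no host cells (from 21.7 to 6.12 TPM, log2 -1.53, limma adjusted p = 0.0142), so its source in tumors is not known. Of 15 macrophage genes, 2 were higher, 12 lower and 1 not passed, and the counts were 2 and 12 adjusted over the list alone. Inflammatory cytokines and chemokines followed with Ccl2 (-1.03), which attracts monocytes, Cxcl3 (-1.16), Ccl7 (-1.01) and Tnf (-0.67), of which Ccl2 and Ccl7 are also expressed in both cultured lines: 1 of 13 was higher, 5 lower and 7 not passed, and also 1 and 5 adjusted over the list alone. Among 7 NK cell genes 3 were lower, the activating receptors Ncr1 (-0.91) and Klrk1 (-0.82) and Klra7 (-0.91), 4 were not passed, and 3 were lower adjusted over the list alone. Set against other genes by limma camera, the lists had adjusted p = 0.000136 for macrophage, 0.0236 for inflammatory cytokines and chemokines and 0.0273 for NK cell. With an estimated correlation none held: macrophage and the cytokine list had adjusted p = 0.136 with an estimated correlation, and the NK cell list had adjusted p = 0.262 with an estimated correlation. The NK cell call also ended after quantile normalization (adjusted p = 0.0695). The macrophage score, the mean log2(TPM + 1) of members per tumor, was 5.29 ± 0.33 (SD) in parental and 4.61 ± 0.20 in resistant tumors, a difference of -0.68 with 12 of 12 resistant tumors below the parental mean (permutation p = 4e-05, adjusted p = 0.000320). The score difference was -0.38 for inflammatory cytokines and chemokines, also in 12 of 12 tumors, where the permutation p of 1e-05 is the smallest that 100000 resamples can give, and -0.56 for NK cell (adjusted p = 0.00464).

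Cytotoxic T cell and MHC class II genes were mostly not called. Prf1, the pore-forming protein of killer cells, fell from 13.6 to 4.93 TPM (log2 -1.24 ± 0.19 SE), and the chemokine Ccl5 fell by 0.78. The cultured lines express Ccl5 themselves, with averages of 33.6 TPM in parental and 125 TPM in resistant culture, so its source in tumors is not known. Of 12 cytotoxic T cell genes 3 were lower and 9 not passed, with 3 lower adjusted over the list alone, and the list missed the threshold (camera adjusted p = 0.0517). Its score difference did pass (-0.33, permutation test, adjusted p = 0.0199). Of 9 MHC class II genes only H2-Oa (-0.78) was lower, 8 were not passed, 1 was lower adjusted over the list alone, and the list missed the threshold (0.0552), as did its score difference (-0.40, permutation test, adjusted p = 0.0656). Cd74, the class II invariant chain, was not called (-0.60, adjusted p = 0.131), but was without parental tumor replicate 3 (-0.82, 0.00794). With the 4 parental tumors of highest GC index left out, the cytotoxic T cell list (camera adjusted p = 0.0172) and the MHC class II list (0.0106) were called, and so was the class II score (permutation test, adjusted p = 0.00573). These list calls used the preset correlation. An estimated correlation was not run without those tumors, and over all tumors it left no list called.

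Part of the interferon-induced genes were higher in resistant tumors, and at least as many were not called. Ddx58, which senses viral RNA, rose from 88.3 to 128 TPM (log2 0.54 ± 0.10 SE), Irf9, which binds interferon-stimulated promoters, from 51.9 to 76.3 TPM (0.56 ± 0.10), and Oasl2 from 478 to 713 TPM (0.59 ± 0.11). Ifi27l2a went against them, from 275 to 116 TPM (-1.27 ± 0.18). Of 26 type I interferon response genes 12 were higher, 1 lower and 13 not passed, and 14 and 1 adjusted over the list alone (camera adjusted p = 0.00250; adjusted p = 0.456 with an estimated correlation). Of 12 interferon receptor and JAK-STAT genes 6 were higher and 6 not passed, with Stat2 (0.55) and the phosphatase gene Ptpn2 (0.47) beside Jak2, and 7 were higher adjusted over the list alone (0.0133; adjusted p = 0.262 with an estimated correlation). Of 21 interferon gamma response genes 8 were higher, among them the GTPases Iigp1 (0.86) and Irgm1 (0.39), 1 was lower, the tryptophan-degrading enzyme Ido1 (-1.61), and 12 were not passed. Adjusted over the list alone 11 were higher and 1 lower, and the list missed the threshold (0.0726). Of 16 MHC class I antigen processing genes 4 were higher, with the peptide-loading chaperones Calr (0.58) and Pdia3 (0.44) and the proteasome activator Psme2 (0.42), 1 was lower and 11 were not passed, against 4 and 2 adjusted over the list alone. The call for Psme2 ended with the GC index as a covariate (0.27, adjusted p = 0.107). The MHC class I median was -0.08 and its mean 0.06, so they differ in sign, and the camera direction was up (adjusted p = 0.773). The score differences were 0.29 for the type I list, 0.32 for the JAK-STAT list in 12 of 12 tumors, and 0.06 for MHC class I (permutation test, adjusted p = 0.0121, 0.000320 and 0.304). Without the 4 parental tumors of highest GC index the type I difference was 0.19 and not called (permutation test, adjusted p = 0.0646).

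Part of the stromal and TGF-beta genes were also higher in resistant tumors. Pdgfrb, a receptor of fibroblasts and pericytes, rose from 54.9 ± 29.5 to 176 ± 21.6 TPM (log2 1.79 ± 0.17 SE, limma adjusted p = 1.87e-08), Col3a1, a fibrillar collagen, from 281 to 526 TPM (1.05 ± 0.23), and Col6a3 (0.85) and the collagen crosslinking enzyme Lox (1.11) rose with them. Inhba, the activin A subunit, rose from 29.9 ± 9.32 to 96.6 ± 26.5 TPM (1.68 ± 0.17), with the growth factor Tgfb2 (1.07) and the TGF-beta targets Smad7 (1.01) and Id3 (0.77). In culture, where there are no host cells, Pdgfrb (1.81), Inhba (3.96) and Tgfb2 (1.17) rose too, while Col3a1 fell (-2.34). Col6a3 stood between 328 and 609 TPM in resistant culture. The source of Pdgfrb, Inhba, Tgfb2 and Col6a3 in tumors is therefore not known. Of 15 fibroblast and matrix genes 9 were higher and 6 not passed, and 9 were higher adjusted over the list alone (camera adjusted p = 0.00805; adjusted p = 0.262 with an estimated correlation). Of 16 TGF-beta response genes 7 were higher and 9 not passed, and 7 were higher adjusted over the list alone (0.0133; adjusted p = 0.136 with an estimated correlation). The scores rose by 0.70 for fibroblast and matrix (permutation test, adjusted p = 0.00116) and by 0.41 for TGF-beta (adjusted p = 0.000107), each in 12 of 12 tumors.

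Most Wnt targets and part of the oxidative phosphorylation and stress genes were lower. Notum, a secreted Wnt antagonist induced by Wnt signaling, fell from 8.64 to 0.441 TPM (log2 -2.33 ± 0.37 SE), with Tcf7 (-0.89), Lef1 (-0.65) and Myc (-0.50). Of 7 Wnt beta-catenin targets 5 were lower and 2 not passed, and 5 were lower adjusted over the list alone (limma camera adjusted p = 0.00805; adjusted p = 0.136 with an estimated correlation). Nos2, the inducible nitric oxide synthase, fell from 10.1 to 4.62 TPM, and the ATP-degrading enzyme gene Entpd1 fell by 0.80, a call that ended with Ptprc as a covariate (-0.50, adjusted p = 0.0914). With Ido1, 3 of 5 adenosine, tryptophan and arginine suppression genes were lower and 2 not passed, and 4 were lower adjusted over the list alone (0.0188; adjusted p = 0.136 with an estimated correlation). The oxidative phosphorylation genes Ndufa4 (-0.58), Cox5a (-0.45) and Sdhb (-0.67) fell by smaller amounts. Of 14 such genes 1 was higher, 6 lower and 7 not passed, also 1 and 6 adjusted over the list alone (0.0133; adjusted p = 0.262 with an estimated correlation). In the integrated stress response Trib3 and Atf3, both induced by ATF4, each fell by 0.75. There 5 of 13 were lower and 8 not passed, and 5 were lower adjusted over the list alone (0.0135; adjusted p = 0.331 with an estimated correlation). Without the 4 parental tumors of highest GC index the stress list and the adenosine list were not called (both 0.0742; the stress list had 0.133 with the GC index as a covariate), and neither were the stress genes Phgdh (-0.38, adjusted p = 0.0620, against -0.62) and Chac1 (-0.34, 0.163, against -0.67; -0.20, 0.219 with the GC index as a covariate). Score differences were -0.51 for Wnt targets, -0.50 for the adenosine list, -0.20 for oxidative phosphorylation and -0.33 for the stress list (permutation test, adjusted p = 0.000914, 0.000107, 0.000914 and 0.00188). The Wnt and adenosine scores average 13 and 10 members, some too low to be tested. Their sizes depend on the pseudocount, with -0.86 and -0.83 at 0.1. Without the 4 tumors the score differences were -0.35 for Wnt targets, -0.49 for the adenosine list, -0.17 for oxidative phosphorylation and -0.24 for the stress list. All were still called (permutation test, adjusted p = 0.00672, 0.00024, 0.00672 and 0.0165). Cell cycle genes showed 4 of 21 higher, with the cyclin gene Ccna2 (0.59) and the spindle checkpoint gene Bub1b (0.52), 1 lower and 16 not passed, the same counts adjusted over the list alone, and no list call (0.267). The call for the lower gene, Top2a (-0.46), ended with the GC index as a covariate (-0.13, adjusted p = 0.291). Their score did rise, by 0.11 in 11 of 12 tumors (permutation test, adjusted p = 0.0130). Skeletal muscle genes showed 3 of 10 higher and 7 not passed, 4 higher adjusted over the list alone, and no list call (0.0676). The 3 calls, for Ckm, Atp2a1 and Myh4, ended in the rank-sum test (adjusted p = 0.0842, 0.0588 and 0.127). Those for Atp2a1 and Myh4 ended in 15 and 21 of the alternatives, most of them leaving out 1 tumor.

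**Figure D2:**
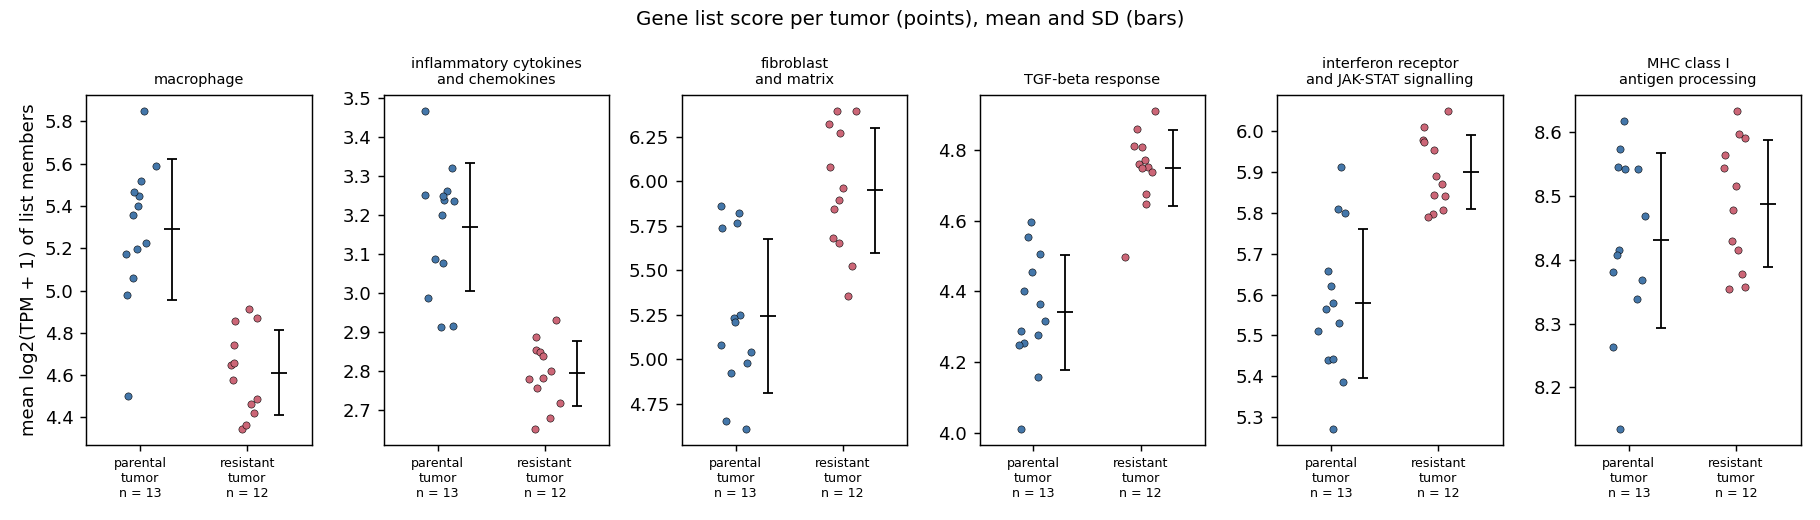
Score of 6 gene lists per tumor, as the mean log2(TPM + 1) of the members; points are tumors, and bars give the mean and SD of 13 parental and 12 resistant tumors. The macrophage score averaged 5.29 in parental and 4.61 in resistant tumors, and the MHC class I scores overlapped.

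Tumors of the parental line with higher cytotoxic T cell scores had higher interferon gamma scores. The cytotoxic T cell list holds Ifng itself, and Ccl5, which the cultured lines also express. Its score is therefore no measure of T cells alone, and part of this relation may be built in. Across the 13 parental tumors Pearson r was 0.806 (permutation p = 0.000260, adjusted 0.00104) and Spearman rho 0.775 (p = 0.00273, adjusted 0.0109) over 8 relations computed. The interferon gamma score and the MHC class I score gave r = 0.885 (permutation p = 3e-05, adjusted 0.000240) and rho = 0.841 (p = 0.000650, adjusted 0.00520) in the same tumors. Without the 2 tumors farthest from the median the coefficients were 0.605 (permutation p = 0.0351, adjusted 0.141) and 0.736 (p = 0.0109, adjusted 0.0874). Neither adjusted call held in that setting. Across the 12 resistant tumors r was 0.626 (permutation p = 0.0274, adjusted 0.0731; rho 0.462, p = 0.133) and 0.578 (p = 0.0478, adjusted 0.0956; rho 0.587, p = 0.0486). Without the 2 tumors farthest from the median these were 0.431 and 0.354 (permutation p = 0.216 and 0.311). The difference between the lines was not tested. Without the 4 parental tumors of highest GC index, r over the other 9 was 0.868 for cytotoxic T cell with interferon gamma scores and 0.887 for interferon gamma with MHC class I scores (exact permutation p = 0.00144 and 0.000631, adjusted 0.00289 and 0.00252). For the second relation these 4 include both tumors farthest from the median, replicates 2 and 3, so its call does not rest on them alone. For the first relation, replicate 10 stayed in. The fibroblast score was not related to the cytotoxic T cell score in parental (r = -0.211, rho = -0.159, permutation p = 0.498 and 0.604) or resistant tumors (r = 0.217, rho = 0.210, p = 0.494 and 0.513). Neither was the cell cycle score, in parental (r = -0.372, rho = -0.126, permutation p = 0.202 and 0.684) or resistant tumors (r = 0.0345, rho = 0.0979, p = 0.914 and 0.767). Without the 2 farthest tumors r for the fibroblast score was -0.110 and 0.195, and for the cell cycle score 0.0223 and 0.0864, in parental and resistant tumors.

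The cultured lines were compared without host cells. Dcn, the matrix proteoglycan decorin, rose from 4.24 ± 3.64 TPM (SD, n = 2) in parental culture to 589 ± 239 TPM (n = 5) in resistant culture, and Mmp9, a matrix-degrading protease, from 0.958 ± 1.25 to 134 ± 36.3 TPM. Acsl5, a fatty acid ligase gene, rose from 0.634 ± 0.626 to 47.0 ± 4.26 TPM. Blnk, an adaptor of B cell receptor signaling, fell from 106 ± 33.2 to 1.09 ± 1.59 TPM, and the neuronal microtubule gene Map2 from 42.3 ± 11.3 to 0.496 ± 1.09 TPM. The limma log2 fold changes were 6.87 ± 0.54 (SE) for Dcn (adjusted p = 0.000187), 6.22 ± 0.38 for Mmp9 (7.08e-05), 4.93 ± 0.23 for Acsl5 (1.00e-05), -5.88 ± 0.51 for Blnk (0.000261) and -5.04 ± 0.50 for Map2 (0.000480). Stxbp2 (5.37) and Cd200 (4.96) also rose, and Cyct (-5.91), Fndc3c1 (-5.68) and the milk casein gene Csn3 (-4.89) fell. The calls for Cyct and Fndc3c1 ended without parental culture replicate 1 (limma adjusted p = 0.0737 and 0.101) or replicate 2 (0.0740 and 0.0867). Of 11201 genes tested with limma, 689 were higher and 901 lower in resistant culture, 346 and 557 of them by at least 2-fold. Leaving out 1 parental culture library, replicate 1 or 2, left 231 or 302 higher and 582 or 276 lower. Without resistant culture replicate 3 or 4, 453 or 421 were higher. Without resistant culture replicate 1 the counts rose to 924 higher and 1192 lower.

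Of the fixed genes Jak1 was called in culture (0.59 ± 0.14 SE, limma adjusted p = 0.0249), but not without parental culture replicate 1 (0.48, 0.136) or replicate 2 (0.70, 0.0670). H2-D1 missed the threshold (-0.53, adjusted p = 0.0585) and passed without parental culture replicate 1 (-0.79, 0.0380), but was -0.28 (0.365) without replicate 2. It also passed with quantile normalization (0.0482) and median-of-ratios scaling (0.0483). Cd274 (-0.56, adjusted p = 0.204), B2m (0.04, 0.923), H2-K1 (-0.07, 0.814), Jak2 (-0.06, 0.890), Irf1 (0.19, 0.473) and Ifngr1 (-0.25, 0.643) were not called. The signs of B2m, H2-K1, Jak2 and Ifngr1 changed when 1 parental culture library was left out. Cd8a and Gzmb were listed at 0 in all 7 cultures, and Ifng, Pdcd1, Foxp3 and Ptprc were too low to be tested.

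Among gene lists in culture, the TGF-beta response list was called, though most of its genes were not. Inhba rose from 3.06 ± 2.26 to 58.3 ± 13.0 TPM (log2 3.96 ± 0.33 SE, limma adjusted p = 0.000228). With Tgfbr1 and Tgfb2 among them, 4 of 13 TGF-beta genes were higher and 9 not passed, and 6 were higher adjusted over the list alone (camera adjusted p = 0.0180; adjusted p = 0.505 with an estimated correlation). Without parental culture replicate 1 the calls ended for Tgfbr1 (0.71, adjusted p = 0.0605) and Tgfb2 (1.04, 0.0612). The interferon-induced chemokine Cxcl10 rose by 1.83 ± 0.31 on the log2 scale, or by 1.13 without parental culture replicate 1. Of 17 interferon gamma response genes 3 were higher and 14 not passed, and 7 were higher adjusted over the list alone (camera adjusted p = 0.0468; adjusted p = 0.736 with an estimated correlation). The other members, Batf2 (2.21) and Socs1 (1.23), were not called without parental culture replicate 1 (adjusted p = 0.101 and 0.161) or replicate 2 (0.0546 and 0.114). The T cell checkpoint receptors Havcr2 (-2.33) and Tigit (-2.06) fell, 2 of 4 tested genes with 2 not passed and 3 lower adjusted over the list alone (camera adjusted p = 0.0228; adjusted p = 0.458 with an estimated correlation). Inflammatory cytokines and chemokines just missed the threshold (0.05003), with 3 of 10 higher, 7 not passed and 6 higher adjusted over the list alone. None of the 3 calls, for Il11, Csf1 and Ccl2, was kept without parental culture replicate 2 (adjusted p = 0.0862, 0.206 and 0.283). Fibroblast and matrix genes were not called as a list (0.0846), with 3 of 9 higher, Pdgfrb (1.81) among them, 1 lower, Col3a1 (-2.34), against its rise in tumors, 5 not passed, and 3 and 1 adjusted over the list alone. The calls for Col3a1 and Col6a3 (1.29) ended without parental culture replicate 1 (adjusted p = 0.103 and 0.189) or 2 (0.152 and 0.0720). MHC class I (0.718) had 1 of 16 lower, 15 not passed and 1 lower adjusted over the list alone, and the call for that gene, Tap1 (-1.09), ended without parental culture replicate 2 (adjusted p = 0.134). The type I interferon list (0.504) had 1 of 24 lower, Oas3 (-1.97), a call that ended in 6 alternatives, 23 not passed and 0 adjusted over the list alone, where fry called 5 lists of all those tested in culture and limma gave 3345 genes an unadjusted p under 0.05.

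The line difference was partly shared between culture and tumors, which have no library in common. Prl2c2, Fam129a, Ncam1 and Cyct were lower, and Dgki, Inhba, Pdgfrb, Dcn and Mmp9 higher, in the resistant line in both settings by at least 2-fold. Itgb4 fell in tumors and was not called in culture, with 3.57 ± 1.81 TPM in parental and 1.68 ± 2.16 TPM in resistant culture. Across 10900 genes tested in both settings the log2 fold changes correlated with Pearson r = 0.478 and Spearman rho = 0.411, as a description, since genes are not independent replicates. Among 1499 genes called in culture r was 0.675, 81.1% had the same sign in tumors, and the slope of tumor on culture was 0.285. Calls in both settings numbered 336 higher, where 117 would overlap if independent, and 362 lower, where 107 would. Opposite calls numbered 15 and 23. At least 2-fold in both, 57 genes were higher, 88 lower and 8 opposite.

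**Figure D3:**
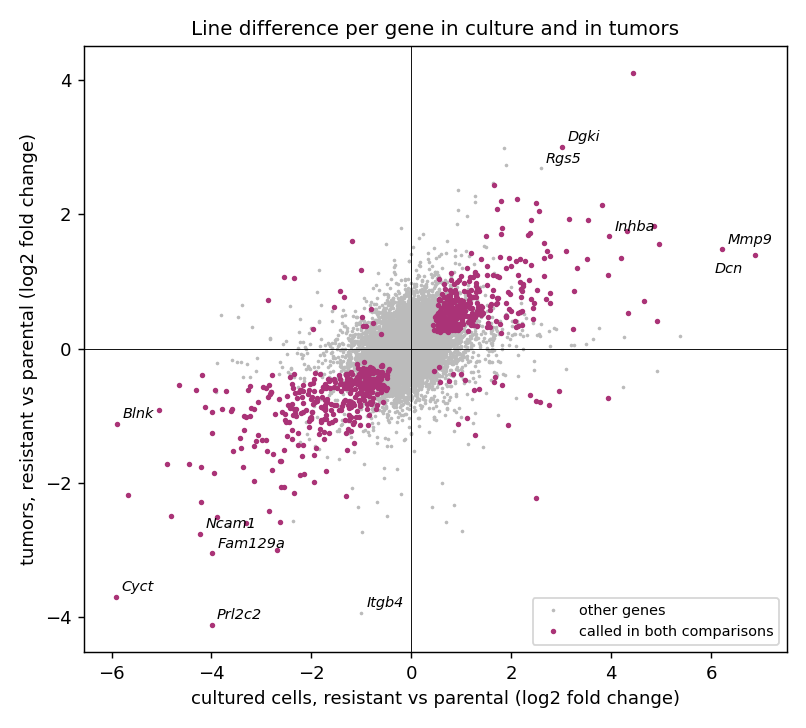
Line difference per gene, resistant against parental, in cultured cells on the x axis and in tumors on the y axis, both as log2 fold change. Points are genes tested in both settings, and colored points were called in both, 336 higher and 362 lower in both.

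Parental tumors were compared with parental cultured cells to show what growth in the animal adds, host cells included. Apoe, the lipid carrier made by macrophages, rose from 1.998 ± 0.201 TPM (SD, n = 2) in culture to 1718 ± 750 TPM (n = 13) in tumors, and Tmsb4x, an actin-binding peptide abundant in leukocytes, from 0.577 ± 0.270 to 972 ± 340 TPM. Ms4a4c, a leukocyte membrane gene, was listed at 0 in both cultures and stood at 254 ± 97.8 TPM in tumors. Nqo1, a detoxifying target of the oxidative stress factor NRF2, fell from 201 ± 57.3 to 14.1 ± 6.64 TPM, and the dehydrogenase gene Adh7 from 108 ± 21.6 to 9.93 ± 6.65 TPM. The limma log2 fold changes were 9.02 ± 0.45 (SE) for Apoe (adjusted p = 7.47e-11), 9.20 ± 0.34 for Tmsb4x (2.57e-12), -3.89 ± 0.54 for Nqo1 (2.77e-05) and -3.60 ± 0.64 for Adh7 (0.000451). The protease Ctss (8.04) and the Fc receptor gene Fcer1g (7.84) also rose, and Sprr1b (-4.27), Slc5a1 (-4.09) and Fndc3c1 (-4.09) fell. Of 14348 genes tested with limma, 2310 were higher and 859 lower in tumors, and without parental culture replicate 1 or 2 these were 1040 or 1377 higher and 366 or 250 lower. Higher genes made up 72.9% of the calls, but 52.1% after quantile normalization, which moved the median of all genes from 0.21 to -0.04. Tumor and culture libraries carry different title series, so a batch and the setting cannot be told apart.

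Interferon and host cell gene lists were among the 27 lists called in this comparison. All 26 type I interferon genes were higher, also adjusted over the list alone, with Ifit3 (4.89 ± 0.28 SE, log2), Mx1 (4.81) and Irf7 (5.38) among them (limma camera adjusted p = 2.35e-18; adjusted p = 0.0721 with an estimated correlation). Of 21 interferon gamma genes 20 were higher and 1 not passed, with Batf2 (5.01), Tgtp2 (5.75) and Gbp2 (4.27), and 21 were higher adjusted over the list alone (2.55e-16). MHC class I genes rose with H2-K1 (2.45) and Tap1 (2.40), and 13 of 16 were higher, 2 lower and 1 not passed, 14 and 2 adjusted over the list alone (6.69e-08). Macrophage genes had 14 of 15 higher and 1 not passed, the same adjusted over the list alone, with C1qa at 7.60 (3.81e-16). Fibroblast and matrix genes had 13 of 15 higher and 2 not passed, and 15 higher adjusted over the list alone, with Postn (4.38) and Col1a2 (4.11) among them (1.58e-09). Endothelial genes had 13 of 14 higher and 1 not passed, also 13 adjusted over the list alone, with the junction gene Pecam1 at 4.04 and Eng at 3.74 (1.46e-11). Cytotoxic T cell genes had 10 of 14 higher and 4 not passed, and 12 higher adjusted over the list alone (5.16e-06; adjusted p = 0.0542 with an estimated correlation), with Ccl5 at 3.82, or 2.26 without parental culture replicate 1. Most cell cycle genes were not called, with 5 of 21 lower, the mitotic cyclin Ccnb1 (-1.93) and Ccna2 (-0.85) among them, 16 not passed, and 6 lower adjusted over the list alone (0.000362). The calls for Pcna (-0.95) and Mcm4 (-0.65) ended without parental culture replicate 1 (-0.72, adjusted p = 0.125, and -0.55, 0.312), and that for Mcm4 also without replicate 2 (-0.75, 0.139).

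Resistant tumors were compared with resistant cultured cells in the same way. Cxcl9, a chemokine induced by interferon gamma, rose from 4.05 ± 2.54 TPM (SD, n = 5) in culture to 637 ± 244 TPM (n = 12) in tumors, and Cd74 from 0.955 ± 0.341 to 267 ± 81.7 TPM. Fgf7, a fibroblast growth factor, fell from 213 ± 60.05 to 22.0 ± 6.12 TPM, and the nucleotide kinase gene Nme1 from 347 ± 39.5 to 49.8 ± 30.2 TPM. The limma log2 fold changes were 7.07 ± 0.29 (SE) for Cxcl9 (adjusted p = 2.53e-14), 7.04 ± 0.23 for Cd74 (9.92e-16), -3.20 ± 0.20 for Fgf7 (1.89e-11) and -2.98 ± 0.32 for Nme1 (1.65e-07). Ms4a4c (7.68), Tmsb4x (7.12) and the surface antigen gene Ly6a (7.02) also rose, and the BMP target Id1 (-3.46), Slco4a1 (-3.36) and the growth factor Ereg (-3.04) fell. Of 12312 genes tested with limma, 4342 were higher and 1847 lower in tumors. Higher genes made up 70.2% of calls, 58.7% with median-of-ratios scaling and 43.7% after quantile normalization, which moved the median of all genes from 0.18 to 0.06 and -0.10.

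Interferon, macrophage and stromal lists were called in the resistant line too. All 26 type I interferon genes were higher, also adjusted over the list alone, with Oas2 at 5.94 ± 0.16 (SE, log2) and Bst2 at 2.48 (limma camera adjusted p = 5.23e-22). Interferon gamma genes had 19 of 20 higher and 1 not passed, also 19 adjusted over the list alone, with Iigp1 at 6.01 (1.67e-14). MHC class I genes had 14 of 16 higher and 2 lower, the same adjusted over the list alone, with Tap1 at 3.25 and B2m at 2.38 (1.95e-07). Macrophage genes had 14 of 15 higher and 1 lower, the same adjusted over the list alone, with C1qa at 6.24 and Csf1r at 4.17 (6.80e-12). Fibroblast and matrix genes had 13 of 15 higher and 2 not passed, and 14 higher adjusted over the list alone, with Col3a1 at 5.68 (3.62e-08). All 14 endothelial genes were higher, also adjusted over the list alone (5.42e-09), and 11 of 12 cytotoxic T cell genes were higher with 1 not passed, and 12 adjusted over the list alone (2.19e-05). Hypoxia genes rose in 13 of 13, also adjusted over the list alone, with the growth factor Vegfa at 1.43 and the carbonic anhydrase gene Car9 at 3.88 (1.98e-06; adjusted p = 0.0871 with an estimated correlation). Oxidative phosphorylation genes had 1 of 14 higher, 9 lower and 4 not passed, and 1 and 10 adjusted over the list alone, with Ndufa4 at -0.78 (0.000474; adjusted p = 0.0871 with an estimated correlation). Cell cycle genes had 1 of 21 higher, 10 lower and 10 not passed, the same adjusted over the list alone, with Pcna at -0.69 and Ccnb1 at -1.04 (0.000688). The oxidative phosphorylation and cell cycle calls ended after quantile normalization (adjusted p = 0.0817 and 0.0936).

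Whether the line difference itself differed between tumors and culture was tested as an interaction over all 32 libraries. Tumors also hold host cells, so for a gene that these express the interaction does not isolate the MC38 cells. Blnk was 106 TPM in parental and 1.09 TPM in resistant culture, but 12.9 ± 4.69 (SD, n = 13) and 5.03 ± 1.28 TPM (n = 12) in tumors, an interaction of 4.76 ± 0.51 (SE, log2, limma adjusted p = 7.87e-08). Dcn differed far more between the lines in culture than in tumors, where it stood at 240 ± 172 and 477 ± 154 TPM (-5.48 ± 0.95, adjusted p = 0.000239). Slc4a5, a bicarbonate transporter gene, was 1.07 TPM in parental culture and between 29.0 and 62.2 TPM on average in the other groups (-5.26 ± 0.45, 4.05e-10). The others were the extracellular superoxide dismutase gene Sod3 (4.31), Map2 (4.13), the basement membrane collagen Col4a1 (4.10), Sprr1b (4.08), Stxbp2 (-5.18), the T cell adaptor Fyb (-4.82) and Mmp9 (-4.74). Of 15061 genes tested with limma, 361 had a positive and 243 a negative interaction. Without parental culture replicate 2 these were 108 and 134, and without replicate 1 the negative count was 147.

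Inflammatory cytokines and chemokines gave the strongest list interaction. Ccl2 rose from 204 to 461 TPM on average from parental to resistant culture, but went from 237 to 116 TPM in tumors (-2.14 ± 0.33 SE, log2, limma adjusted p = 4.52e-05), and Il11, a fibrosis-associated cytokine, had -1.77. The culture rise of Ccl2 by itself ended without parental culture replicate 1 (1.26, adjusted p = 0.178) or replicate 2 (0.96, 0.283). Of 16 such genes 3 were lower and 13 not passed, and 7 were lower adjusted over the list alone (camera adjusted p = 2.18e-05, and 0.000395 with an estimated correlation). The call for the other lower member, Tnf (-1.29, adjusted p = 0.0368), ended without parental culture replicate 1 (0.164) or 2 (0.282), without resistant culture replicate 4 (0.0766) or 5 (0.0839), and with no filter (0.0559). No other list held with an estimated correlation. Immediate early genes had 3 of 10 lower and 7 not passed, and 4 lower adjusted over the list alone, with Egr1 at -1.53 (0.000333; adjusted p = 0.448 with an estimated correlation). The call for Jun (-1.70) ended without parental culture replicate 1 (adjusted p = 0.0749) or 2 (0.0919), and that for Junb (-1.29) without replicate 2 (0.109). Type I interferon genes had 3 of 26 higher and 23 not passed, and 6 higher adjusted over the list alone (0.000751; adjusted p = 0.593 with an estimated correlation). The members Oas3 (2.26), Oas2 (2.14) and Bst2 (1.17) were not called without parental culture replicate 2 (1.09, adjusted p = 0.109, then 0.78, 0.540, and 0.47, 0.737). Cultures hold no host cells, so genes made only by macrophages repeat here their line difference in tumors. Macrophage genes had 2 of 15 lower and 13 not passed, and 3 lower adjusted over the list alone (0.00110; adjusted p = 0.448 with an estimated correlation). Its members C1qa (-1.35) and Ms4a7 (-1.67) were not called without parental culture replicate 1 (adjusted p = 0.166 and 0.0977) or replicate 2 (0.163 and 0.164). Cholesterol synthesis genes had 2 of 13 higher and 11 not passed, and 3 higher adjusted over the list alone (0.000751; adjusted p = 0.448 with an estimated correlation). Among them the call for Fdft1 (1.03) ended in 9 alternatives. Hypoxia genes had 0 of 13 called and 3 higher adjusted over the list alone (0.00185; adjusted p = 0.463 with an estimated correlation). For Wnt targets 3 of 12 were lower and 9 not passed, and 1 was higher and 4 lower adjusted over the list alone, with Tcf7 at -1.60, or -1.58 without parental culture replicate 2 (adjusted p = 0.0713). The calls for Myc (-1.08) and Notum (-3.19) ended without either parental culture library (adjusted p = 0.0501 and 0.355 for Myc, 0.192 and 0.284 for Notum). The Wnt list had adjusted p = 0.0291, and adjusted p = 0.448 with an estimated correlation. B and plasma cell genes had 1 of 7 lower, Cd79a (-2.61), with 6 not passed and 1 lower adjusted over the list alone (0.0483; adjusted p = 0.448 with an estimated correlation). In mismatch repair 0 of 10 were called and 2 were higher adjusted over the list alone (0.0444; adjusted p = 0.448 with an estimated correlation). In the integrated stress response 0 of 13 were called and 2 were lower adjusted over the list alone (0.0273; adjusted p = 0.448 with an estimated correlation). The Wnt, B and plasma cell, mismatch repair and stress lists were also not called with a pseudocount of 0.1 (adjusted p = 0.0628, 0.115, 0.0918 and 0.0930) or after quantile normalization (0.0959, 0.152, 0.0926 and 0.0524). Beside these counts of 0, limma gave 2220 genes an unadjusted interaction p under 0.05, and fry called 1 list.

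Tubb5, an abundant tubulin gene, varied widely among parental tumors together with a GC index of each library. It lay between 15.7 and 454 TPM in parental tumor replicates 2, 3, 7 and 8, and between 671 and 1271 TPM in the other 9. The index, the median log2 level of GC-rich genes minus that of GC-poor genes, was above 0.5 in those 4 tumors. It averaged 0.158 ± 0.406 (SD) in parental and -0.185 ± 0.272 in resistant tumors. Resistant tumor replicates 3 and 12 also had low Tubb5, at 341 and 404 TPM, with an index of 0.273 and 0.210, and were not left out. Without the 4 parental tumors limma called 1718 genes higher and 1626 lower in resistant tumors, and 71.4% of the calls from all tumors were kept.

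**Figure D4:**
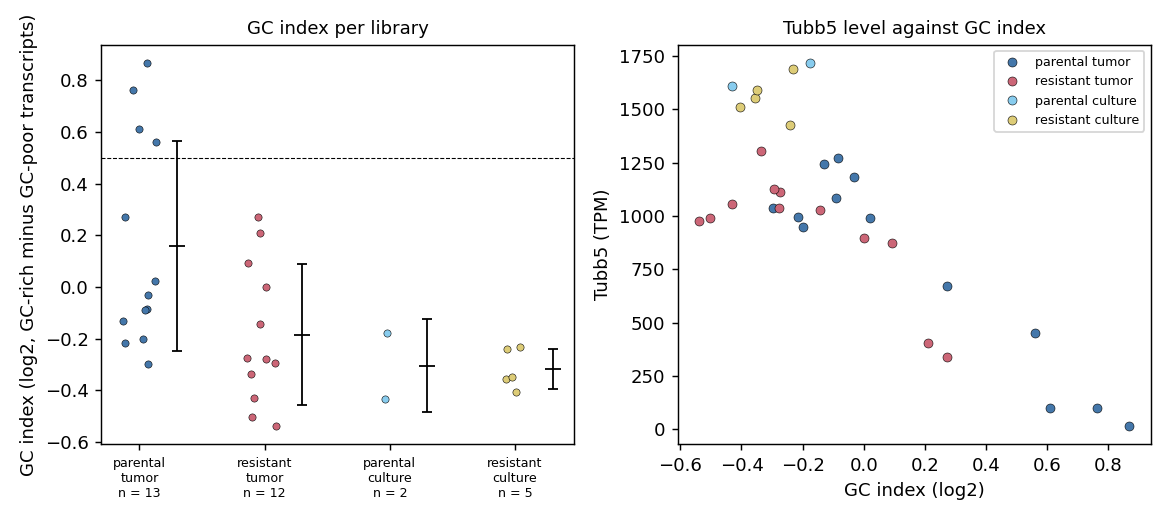
GC index per library by line and setting, with mean and SD bars and a dashed line at 0.5, and the Tubb5 level in TPM against the index. The 4 parental tumors above 0.5 had Tubb5 between 15.7 and 454 TPM.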

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

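The test of admixture and the GC index tests rest on measures chosen only after the result was seen, although the bounds for the GC tests were set before their outcome was known. The genes named from the set of 24 were also chosen after their values were seen.

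Blnk, Map2, Cyct and Fndc3c1, which parental culture expresses and the other resistant cultures nearly lack, were raised in resistant culture replicate 1 alone. That library lay apart from the other 4 by Dixon's ratio, the gap to the nearest library over the group's range, with 0.828 for Blnk, 0.968 for Map2, 0.915 for Cyct and 1 for Fndc3c1 against a critical value of 0.71. The same replicate was apart for Col4a1 (0.734), Egr1 (0.770), Fcgr1 (1), Ifi27l2a (1), Il11 (0.825), Jak2 (0.838), Socs1 (0.713), Sod3 (0.870) and Stxbp2 (0.721). Chance sets apart about 1 in 20 groups, or 5.5 of 110 measures, and all 13 found here were replicate 1. Many of these measures are genes named from comparisons that used the same libraries, and genes of 1 library vary together. The count is therefore no test against chance. A share of parental cells could explain a library between the lines. From 56 genes high in the parental line the median parental share of replicate 1 was 0.187, and from 26 genes high in the resistant line it was 0.547. A plain mixture with the cells in the other cultures would give the same share from both sides, and the difference was -0.360 (bootstrap interval -0.537 to -0.187). Replicates 2 to 5 had smaller differences of -0.0575, 0.199, 0.153 and -0.0945. The intervals of replicates 3 (0.00465 to 0.383), 4 (0.0540 to 0.315) and 5 (-0.189 to -0.0361) also left out 0. The reference for replicates 2 to 5 included replicate 1, so their departures from 0 may come in part from it and are no clean baseline. Without such a baseline, the larger departure of replicate 1 argues only weakly against a plain mixture. An unequal mixture or a change within that culture stays open, and no biological explanation was tested, since the design gives none within a group.

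Dcn, Mmp9 and Stxbp2 differed between the lines far more in culture than in tumors, and so did Blnk and Map2 in the other direction. The difference between the settings was tested as an interaction with limma, which called 361 genes positive and 243 negative. The log2 values were 4.76 for Blnk, 4.31 for Sod3, 4.13 for Map2, 4.10 for Col4a1 and 4.08 for Sprr1b, and -5.48 for Dcn, -5.26 for Slc4a5, -5.18 for Stxbp2, -4.82 for Fyb and -4.74 for Mmp9. Called lists, by limma camera adjusted p, were inflammatory cytokines and chemokines (2.18e-05), immediate early genes (0.000333), type I interferon response (0.000751), cholesterol synthesis (0.000751), macrophage (0.00110), hypoxia (0.00185), integrated stress response (0.0273), Wnt targets (0.0291), mismatch repair (0.0444) and B and plasma cells (0.0483). Only the cytokine list held (0.000395 with an estimated correlation), and the other 9 had adjusted p = 0.448 to 0.593 with an estimated correlation. Cultures hold no host cells, so the macrophage list can be called here through its line difference in tumors alone. For any gene that host cells express in tumors, the interaction does not isolate the MC38 cells. A batch that follows the setting cannot be told apart from the setting.

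Stxbp2, Cd200, Rgs5, Fas and Icam1 are among 24 genes under 1 TPM in both parental cultures but averaging at least 5 TPM in parental tumors, resistant tumors and resistant culture. Host cells may supply these transcripts in parental tumors. The score of the set followed a leukocyte score across the 13 parental tumors with r = 0.647 (permutation p = 0.0282, rho 0.209), which meets the bound set in advance. The interval of that r ran from -0.329 to 0.917. The relation rests on 2 tumors, without which r was -0.137 (interval -0.632 to 0.603), so a further requirement that the relation hold without them was applied after the result was seen, and was not met. The host cell source stays open.

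Prl2c2, Itgb4, Has2 and the rest of the tumor line difference were weighed against chance, library quality and leukocyte content. Of 100 splits of the 25 tumors only the real one gave as many called genes, 3647, and the highest other gave 2556. A share of 1 in 100 is the smallest that this number of splits can give. Splits cannot tell the line from a batch that follows it, and the title numbers of the lines do not overlap. With the GC index as a covariate 94.9% of genes of at least 2-fold kept their call and direction. This argues against GC-related library quality as the whole cause for them, though they were chosen by their size in the same tumors. Other aspects of quality were not tested. Among genes under 2-fold 65.3% kept their call and direction, between the bounds set in advance, so quality and line cannot be told apart for that part. With Ptprc as a covariate 99.1% of genes of at least 2-fold kept their call. Ptprc was not called between the lines and is 1 gene that need not follow each leukocyte type. This covariate could therefore remove little of a line difference, and it cannot decide on leukocyte content. For resistant tumors against culture, 1 of 100 splits, the real one with 6189 genes, gave as many, and the highest other gave 2864.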

How the results depend on the processing

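The GC index covariate and the fits without the 4 tumors of high GC index were chosen only after the data were seen. Prl2c2, Itgb4, Has2, Rgs5 and the other large tumor line differences kept their calls under every alternative run, Col1a1 excepted, and so did all genes named for resistant tumors against culture. For named genes 5352 of 5536 values (96.7%) kept direction and side of the threshold, 124 lost the call, 40 gained it and 20 changed direction. For gene lists 648 of 797 (81.3%) did, 79 lost, 47 gained and 23 changed direction, and for list scores 111 of 128 (86.7%), 7 lost, 5 gained and 5 changed direction. None that changed direction had been called, and 2 were called after the change. Between tumors the GC index covariate turned Cd274 to -0.51 (adjusted p = 0.0128), B2m to 0.0816, H2-K1 to 0.11, Irf1 to 0.11, Ifngr1 to -0.0230 and Ifng to -0.10. Cd274 was -0.10 with array weights, and Cd8a 0.0389 with Ptprc as a covariate, which gives Ptprc itself no value. Without the 4 tumors Cd274 was -0.35, H2-K1 0.00777, Irf1 0.0532 and Ifngr1 -0.0231. Leaving out 1 library gave ranges of -0.0102 to 0.215 for Ifng between tumors, -0.35 to 0.44 for B2m, -0.41 to 0.26 for H2-K1, -0.44 to 0.32 for Jak2 and -0.79 to 0.29 for Ifngr1 in culture, and -0.0127 to 3.12 for the Car9 interaction. Lists are judged by their test's direction and given here by their median log2 value, whose sign can differ. With quantile normalization these were glycolysis between tumors 0.0727, epithelial 0.0785 for parental tumors against culture, integrated stress response 0.15 and immediate early genes 0.0461 for resistant tumors against culture, and MHC class II 0.0887, regulatory T cell 0.00262 and fibroblast 0.18 for the interaction. With fry they were, for resistant tumors against culture, Wnt targets -0.0324 and integrated stress response 0.0827, the latter then called (adjusted p = 0.00913), and, for the interaction, MHC class II 0.00468 and endothelial 0.0238. A pseudocount of 0.1 gave cholesterol synthesis 0.17 for resistant tumors against culture, and MHC class II 0.19 and fibroblast -0.17 for the interaction. The GC index covariate gave glycolysis 0.22 and immediate early genes -0.0171 between tumors. Without the 4 tumors glycolysis was 0.19 between tumors, epithelial -0.29 for parental tumors against culture and, for the interaction, JAK-STAT 0.00866, fibroblast -0.17, endothelial 0.12, mesenchymal transition 0.13 and mitochondrially encoded genes -0.0602. Scores turned to -0.0389 (mean of z-scores) and -0.11 (without the 4 tumors) for monocyte, 0.0294 (quantile normalization) and 0.10 (without the 4 tumors) for glycolysis, and -0.0292 (pseudocount 0.1) for mesenchymal transition. Correlations with the cytotoxic T cell score, none called, turned for cell cycle to -0.102 in resistant tumors after quantile normalization and 0.0223 in parental tumors without the 2 tumors farthest from the median, and for fibroblast to 0.00769 in parental tumors without the 4 tumors. With a 2-fold minimum the counts of genes higher and lower were 186 and 242 between tumors, 346 and 557 in culture, 2013 and 180 for resistant tumors against culture, and 419 lower for parental tumors against culture, by construction fewer. For the following the cause was not tested. With Ptprc as a covariate 3052 genes were higher between tumors. Quantile normalization gave 1491 lower for parental tumors against culture, and 2693 higher and 3470 lower for resistant tumors. Parental tumors against culture had 1520 lower with array weights, 1368 in 1 fit over all libraries and 1419 without the 4 tumors of high GC index. The interaction had 835 positive and 560 negative with array weights, and 368 negative without the 4 tumors. Leaving out each cultured library gave ranges of 231 to 924 higher and 276 to 1192 lower in culture, 1040 to 1377 higher and 250 to 366 lower for parental tumors against culture, and 108 to 443 positive and 134 to 271 negative interactions. Where 1 parental culture remained, it is assumed to vary like the other groups. The correlation of line differences across genes ranged from 0.393 to 0.498. With an estimated correlation between genes the lists called fell from 11 to 0 between tumors, where 4913 genes had an unadjusted limma p under 0.05 and fry called 21 lists, from 3 to 0 in culture (3345 genes, and 5 lists by fry), from 27 to 12 for parental tumors against culture and from 10 to 1 for the interaction. For the interaction fry called 1 list, and a pseudocount of 0.1 and quantile normalization 6 each. With the GC index as a covariate 17 lists were called between tumors. List scores higher in resistant tumors numbered 7, or 4 without the 4 tumors. In resistant tumors quantile normalization raised r to 0.693 for cytotoxic T cell with interferon gamma scores and to 0.687 for interferon gamma with MHC class I scores, both then past the threshold (permutation, adjusted p = 0.0218). In parental tumors these were 0.605 and 0.736 without the 2 tumors farthest from the median, no longer past it. No paired analysis was possible because the labels pair no samples. Depth is unknown, so its limits could not be set.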

Other observations

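The observations here were all chosen after the values were seen. Pax5, the transcription factor of B cells, was present in every library, from 17.4 to 49.0 TPM, including the cultures that hold no host cells. It averaged 18.2 TPM in parental culture, 26.7 TPM in resistant culture and 37.2 TPM in resistant tumors, and ranged from 23.8 to 40.01 TPM in parental tumors. The B cell receptor component Cd79a averaged 0.551 TPM in parental culture and 1.53 TPM in resistant culture.

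Dendritic cell genes and T cell checkpoint receptor genes had lower scores in resistant tumors, by -0.23 and -0.27 (permutation test, adjusted p = 0.0121 and 0.00745), below the parental mean in 12 and 11 of 12 tumors. As lists against other genes neither was called (limma camera, adjusted p = 0.267 and 0.0509; adjusted p = 0.491 and 0.309 with an estimated correlation). The dendritic cell call was lost with the mean of z-scores (permutation test, adjusted p = 0.0706). Batf3 of the dendritic cell list fell in culture too (-1.26, against -1.20 in tumors), and so did Havcr2 and Tigit of the checkpoint receptor list. Cultures hold no host cells, so the source of these lower scores in tumors is not known. The score of mitochondrially encoded genes was higher by 0.31 in 10 of 12 tumors (adjusted p = 0.0327; list test, limma camera, 0.0724), a call lost after quantile normalization and without the 4 tumors of high GC index. The monocyte, glycolysis and mesenchymal transition scores differed by 0.01, -0.01 and 0.00021 (adjusted p = 0.960, 0.960 and 0.998).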
